A study of Homo sapiens with 2 samples.

How the data were processed

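mRNA libraries, prepared with a SMARTer mRNA-seq kit per the labels' protocols, were made from MCF-7 mammospheres after 72 h with nobiletin or with DMSO, the solvent control. The labels give 1 sample per arm, 2 samples in all, and name no replicates. The submitters' processing notes name FastQC 0.11.9 and MultiQC 1.1, which report read quality. The aligner, the quantifier, the test, the genome build and the annotation release are not given in the sources used here.

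The authors deposited a single table of their own comparison of the 2 libraries, with 177816 rows. Each row is a RefSeq transcript with its version, per the file headers and the row identifiers, so the features are transcripts and not genes. The column of log2 fold changes was computed by the authors, per the file headers, and so were the columns of p-values and q-values. How the authors estimated a spread from 1 library per arm is not given in the sources used here. The header does not say which arm is the numerator. A positive log2 fold change is therefore read only as higher in the numerator library, and no value below is assigned to nobiletin or to DMSO. The table also holds 2 columns of per-sample values whose names match neither sample's labels. These were not used in any step, so expression levels enter no value below. Sequencing depth is unknown, and no interval or detection limit that needs a depth is given.

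The deposited log2 fold changes were inspected for their spacing. The most common value, 0.29, was shared by 90510 transcripts (50.9%), of which 89344 had a p-value of 1. The next most common values lay 1.00 and 1.58 above and below it, the spacing of log2 ratios of small whole numbers. Log2 fold changes shared exactly, to 9 decimals, by more than 5 transcripts were therefore treated as coarse and left out of gene values. The rest are called fine-valued. This rule stands in for the minimum level fixed earlier, which was not applied because the per-sample columns were left unused. It was chosen after the table had been seen.

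Transcripts were named through the RefSeq gene table of assembly GRCh38.p14, used for names and gene types only. The versioned accession matched for 169411 transcripts and the accession without its version for 555. The remaining 7850 took the symbol printed in the deposited table. Unnamed loci, genes on the Y chromosome and XIST and TSIX, 24526 transcripts in all, were left out of gene values. A gene's value is the median log2 fold change over its fine-valued transcripts, available for 11963 genes. Where a gene has 1 transcript in the table its value is the deposited value itself, and reads cannot have been divided among its isoforms.

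The design fixed before the data were examined was a log2 ratio computed from levels, with no test, because there is 1 library per arm. The table held comparison columns, so the deposited log2 fold change replaced that ratio. A rule of size, an absolute log2 fold change of 1 or more (2-fold), took the place of a test. No p-value was computed here. The 36 gene lists were also fixed before the data were examined. For each list with at least 5 measured genes, its median was placed among the medians of 10000 random lists of the same size. Random genes were matched on transcripts per gene in the table, in 6 bins starting at 1, 2, 3, 5, 10 and 20. The planned match on mean level was not made, because the per-sample columns were left unused. A mean over both columns would not have needed the arms to be told apart. The percentiles below are therefore not matched on expression level. A list is said to lie outside the random lists when its percentile is below 2.5 or above 97.5. Genes of a pathway vary together, so a percentile describes these 2 libraries and is not a test of treatment. In data simulated on this comparison, with 11963 genes of which 200 were shifted, all drawn lists of 20 genes shifted by 0.5 or 1.5 on the log2 scale, either way, lay outside the random lists (10 lists per shift, 100%). Of 200 lists of 20 unchanged genes, 5.5% did. The simulation permuted log2 fold changes among transcripts, within bins of transcripts per gene and separately for fine and coarse values. It therefore removed any shared variation of genes. The share of 5.5% follows from this construction and is no error rate for lists of pathway genes.

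The planned rule for named genes asked for the authors' adjusted p of 0.05 where no level was available, which no transcript met. The genes named are therefore the 12 highest and 12 lowest values among protein-coding genes with 1 transcript, up to 4 members of each list with the largest absolute value, and members with 1 transcript. This substitute was chosen after the table had been seen. Further members of the lists (CDC45, TYMS, STAT1, RIGI, UGT1A6, NQO1, TIPARP, HMGCR, LDLR, MALAT1, TUG1, OIP5-AS1, CAV1, PGR, B2M and PSMB8) were chosen after their values were seen. GC content and length were taken per gene as medians over its protein-coding transcripts in GENCODE release 29, and their trends were removed with lowess (share 0.3 of genes). Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. Alternatives covered the tie limit, the choice of transcripts, the summary over a list, the random matching, the gene type, centring, the rule of size and the authors' thresholds.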

Results

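MCF-7 is an established human breast cancer cell line of luminal, estrogen receptor-positive type. Grown without attachment it forms floating spheres, called mammospheres, a culture used to enrich for cells with stem-like growth. The study compared the transcriptome of such spheres after 72 h with nobiletin, a polymethoxylated flavone of citrus peel, or with its solvent DMSO, to find genes whose expression differs. There was 1 sample in each arm, so no value below has a replicate error. The dose of nobiletin is not given in the sources used here. Depth is unknown. The deposited comparison covered 177816 RefSeq transcripts of 42738 gene symbols, with log2 fold changes from -10.07 to 9.26. Which arm was the numerator is not stated, so values are described as positive or negative and are not assigned to the drug or the solvent.

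Per transcript, the authors' deposited table held no call after correction for multiple testing. Its lowest q was 0.276, and 0 transcripts had a q below 0.05, with or without a 2-fold minimum. At an unadjusted p under 0.05 the authors' deposited table held 11524 transcripts, 4939 positive and 6585 negative, which is 13.8% of the 83755 transcripts with a p below 1. The smallest absolute log2 fold change among them was 3.41. These transcripts belonged to 5107 genes, of which 1249 had positive ones alone, 1896 negative ones alone and 1962 both. Their share depended on how many transcripts the gene had in the table. It was 0.289% of 7945 transcripts for genes with 1 transcript, 7.61% of 9533 for genes with 3 to 4, and 21.4% of 22340 for genes with 20 or more. Of the 11524 transcripts, 934 (8.10%) were fine-valued and the other 10590 had coarse values. Among fine-valued transcripts alone the shares were lower, at 0.0805% of 2485, 1.34% of 4412 and 6.08% of 6231 in the same order.

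**Figure D1:**
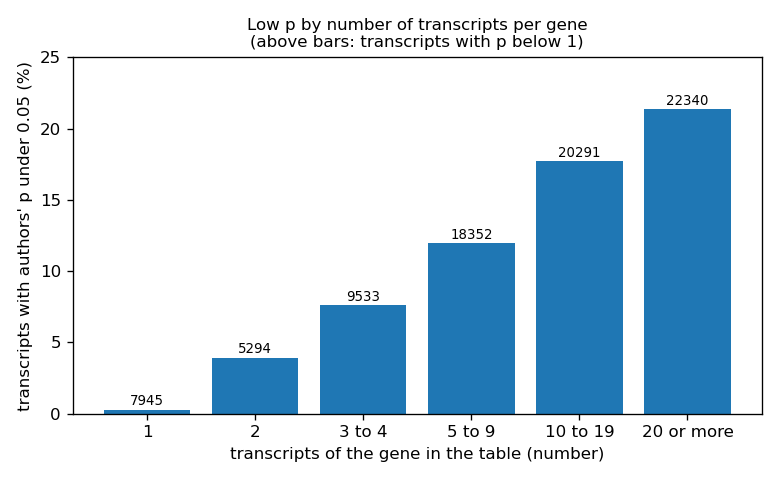
Percentage of transcripts with the authors' unadjusted p under 0.05 (vertical axis) by the number of transcripts that their gene has in the table (horizontal axis). Numbers above the bars count the transcripts with a p below 1, coarse values included; the share climbs from 0.289% for genes with 1 transcript to 21.4% for genes with 20 or more.

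Per gene, most values lay near 0. The median over 11963 genes was -0.02, with an SD over genes of 0.661. The rule of size was met by 318 genes on the positive side (2.66%) and by 611 on the negative side (5.11%). Among the 1756 protein-coding genes with 1 transcript, where isoforms cannot share reads, the median was -0.02, 9 genes were at 1 or higher and 49 at -1 or lower. In the authors' deposited table the lowest of these were SOWAHA (-2.38), the keratin gene KRT17 (-2.13), the mitotic kinesin gene KIF20A (-2.04), KLHDC7B (-1.87), the interferon-induced IFIT2 (-1.84), the epidermal calcium-binding protein gene CALML5 (-1.84) and UBA7, which encodes the activating enzyme for ISG15 (-1.81). They were followed in the authors' deposited table by ARHGDIG (-1.78), the keratin gene KRT6A (-1.73), the immunoproteasome subunit gene PSMB9 (-1.73), the insulin-like growth factor binding protein gene IGFBP5 (-1.72) and the chromosome-associated kinesin gene KIF4A (-1.63). The highest in the authors' deposited table were SULT1A4 (2.13), CCDC39 (2.02), KLHL31 (1.54), RNF224 (1.41), the cytochrome P450 gene CYP1B1 (1.29), the neuropeptide gene UCN (1.17), the secretory-cell transcription factor gene BHLHA15 (1.14), CLDN22 (1.13) and TMEM59L (1.12). CYSRT1 (0.996), POLN (0.95) and the retinol dehydrogenase gene RDH10 (0.91) completed the 12, from the authors' deposited table. The unadjusted p in the authors' deposited table was 0.202 or higher for each of these 24 genes. SULT1A4, KRT17 and KRT6A have near-identical copies or pseudogenes, so their values are uncertain. SOWAHA and ARHGDIG among the lowest, and SULT1A4, CCDC39, KLHL31, RNF224, UCN, TMEM59L and POLN among the highest, 9 of the 24, had values shared exactly by 2 to 5 transcripts of the table. Such ties are the mark of coarse values, so these values are uncertain too.

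Of the 36 gene lists, 31 had at least 5 measured genes, and 17 of these lay outside the random lists, 8 below and 9 above. Chance would place 1.55 outside on average only if the genes of a list varied independently. Genes of a pathway vary together and some lists share genes, so the 17 lists are not a test against chance. Under every alternative run, 7 of the 17 lay outside. These were the S phase, G2 and M phase, interferon, aryl hydrocarbon receptor, cholesterol, ribosomal protein and long noncoding RNA lists. Of the 14 lists inside the random lists, 7 lay outside them under at least 1 alternative. These were the Notch, STAT3, apoptosis, fatty acid synthesis, glycolysis and hypoxia, oxidative phosphorylation and histone lists.

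**Figure D2:**
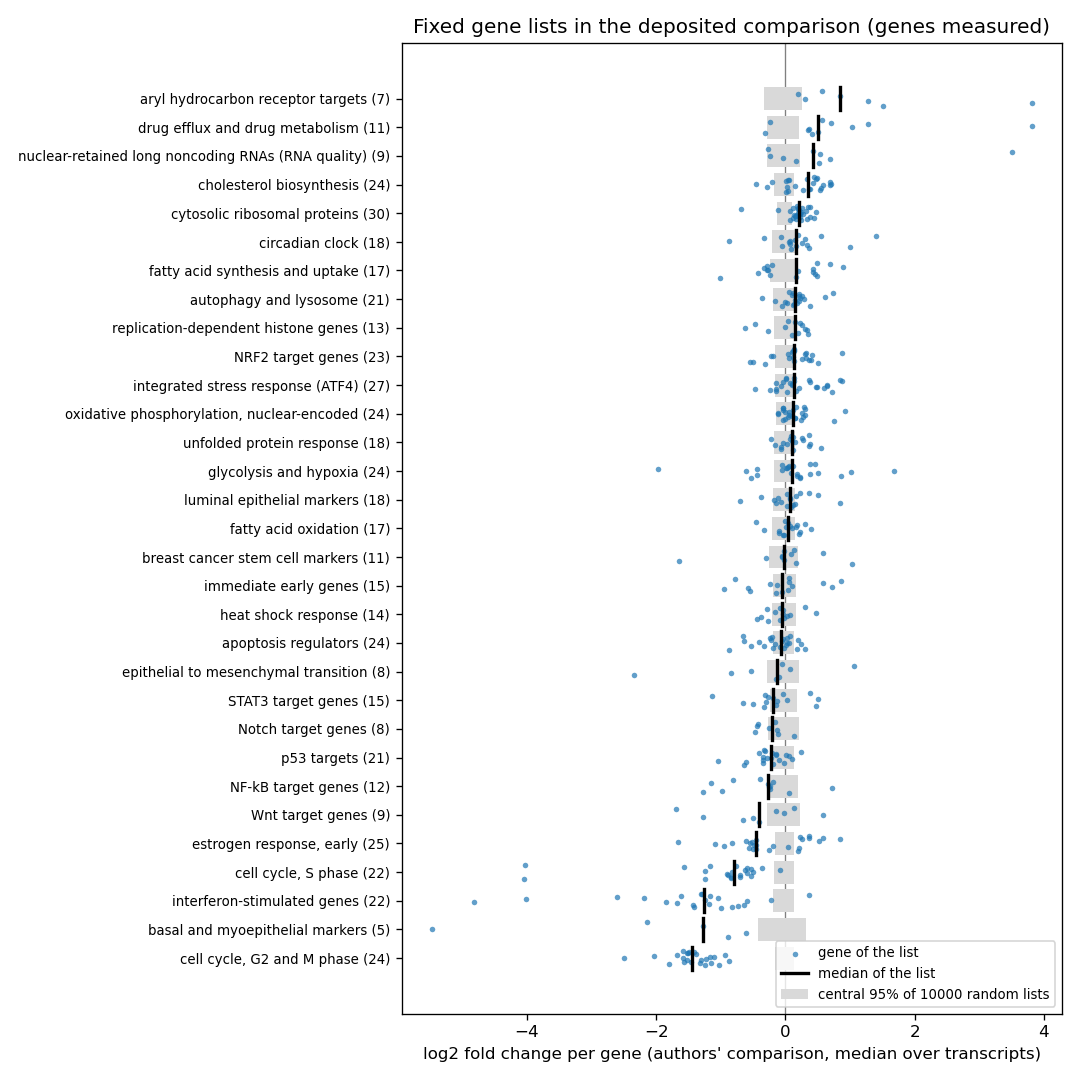
Log2 fold change per gene in the authors' comparison (horizontal axis) for each fixed gene list with at least 5 measured genes (rows, with the number measured). Points are genes, black bars list medians and grey bars the central 95% of 10000 random lists; the G2 and M phase list has a median of -1.44 and the aryl hydrocarbon receptor list one of 0.84.

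Cell cycle genes lay together on the negative side. All 24 genes of the G2 and M phase list were measured and all 24 were negative, with a median of -1.44 (2.71-fold), and 22 were at -1 or lower. The largest absolute values were those of CENPE, a kinetochore motor (-2.50, transcripts between -3.57 and -0.43), and KIF20A (-2.04). AURKB, a mitotic kinase (-1.80), and MKI67, which encodes the proliferation antigen Ki-67 (-1.68, transcripts between -6.38 and -1.48), came next. In the authors' deposited table the list's 7 members with 1 transcript were negative too. Besides KIF20A these were the cyclin genes CCNA2 (-1.56) and CCNB2 (-1.52), the kinase gene PLK1 (-1.52), the checkpoint gene BUB1B (-1.46), CDC20 (-1.31) and KIF11 (-1.17), as the authors' deposited table gives them. All 22 genes of the S phase list were negative as well, with a median of -0.79 (1.73-fold) and 6 at -1 or lower. Among them were RRM2, a subunit of ribonucleotide reductase (-1.57), MCM5, part of the replicative helicase (-1.25), TYMS, thymidylate synthase (-1.17), and CDC45 (-1.24, 1 fine-valued transcript of 13). CCNE2 and UHRF1 had medians of -4.05 and -4.03, but each rested on a pair of transcripts far apart (-7.37 and -0.73, and -6.91 and -1.16). Both lists lay below all 10000 random lists. Of 22 replication-dependent histone genes 13 were measured, with a median of 0.14, inside the random lists (percentile 95.5). The histone list lay above them with protein-coding genes only (percentile 98.2) and at tie limits of 1 (99.1) and 2 (98.7). How fully these mRNA libraries capture histone transcripts is not known, so the value is not read as a measure of S phase.

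Interferon-stimulated genes formed a further group on the negative side. Of the 24 listed, 22 were measured, 21 were negative and 16 were at -1 or lower, with a median of -1.27 (2.40-fold), below all 10000 random lists. The lowest were IFIT3 (-4.82, from transcripts at -7.50 and -2.14), the antiviral GTPase genes MX1 (-4.02, 1 fine-valued transcript of 27) and MX2 (-2.19, 1 of 11), and OAS2, an oligoadenylate synthetase gene (-2.60). IFIT2 (-1.84), the ubiquitin-like modifier gene ISG15 (-1.25) and the tethering factor gene BST2 (-1.001) each have 1 transcript in the authors' deposited table. STAT1, the transcription factor of the pathway, had a median of -1.28 over 10 transcripts that ranged from -2.35 to 2.28. RIGI, an RNA sensor gene, was the positive member (0.37, from transcripts at -1.37 and 2.11).

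Targets of the aryl hydrocarbon receptor, a ligand-activated transcription factor that responds to many planar aromatic compounds, lay on the positive side. All 7 measured genes of the 11 listed were positive, with a median of 0.84 (1.79-fold), above all 10000 random lists, and 3 were at 1 or higher. CYP1A1, its best-known target, had 3 transcripts, at 3.24, 3.82 and 8.85 in the authors' deposited table. The last of these had an unadjusted p of 8.8e-05 and a q of 0.276 in the authors' deposited table. ALDH3A1, an aldehyde dehydrogenase gene, had a median of 1.51, and CYP1B1 stood at 1.29 in the authors' deposited table. The amino acid transporter gene SLC7A5 gave the list's median (0.84, from transcripts between -2.10 and 1.01). SLC7A5 also belongs to the early estrogen response and integrated stress response lists. UGT1A6 (0.57), NQO1 (0.30) and TIPARP (0.19) made up the rest. The list of drug efflux and drug metabolism genes shares CYP1A1, CYP1B1 and UGT1A6 with the aryl hydrocarbon receptor list. Of its 20 genes 11 were measured, with a median of 0.50 and 9 positive. Its efflux transporter gene ABCG2 stood at 1.04, from transcripts between -0.41 and 2.32. That list returned inside the random lists when coarse values were kept (0.18). NRF2 targets had a median of 0.13 over 23 genes, 18 of them positive (percentile 97.8), and returned inside under several alternatives.

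Cholesterol biosynthesis genes had small positive values. Of 24 measured genes 21 were positive, with a median of 0.35 (1.27-fold), above all 10000 random lists, and none met the rule of size. LSS, lanosterol synthase, stood at 0.71, MVD at 0.70, IDI1 at 0.69 and the feedback regulator gene INSIG1 at 0.58 (transcripts between -0.19 and 1.19). HMGCR, which encodes the rate-limiting reductase, stood at -0.28, from transcripts at -0.96 and 0.41. The low-density lipoprotein receptor gene LDLR stood at -0.45, from transcripts between -1.29 and 0.48. Genes of fatty acid synthesis and uptake had a median of 0.16 over 17 genes, 9 positive and 8 negative, inside the random lists. With 10 ties allowed the median was -0.24, below the random lists. At tie limits of 1 and 2 it was 0.19 and 0.16, above them, so its direction was not stable. The desaturase gene SCD stood at 0.70 in the authors' deposited table and ACACA at -1.01 (transcripts between -2.42 and 0.41). Fatty acid oxidation genes had a median of 0.04 over 17 genes. Glycolysis and hypoxia genes had a median of 0.108 over 24 genes. Among them were NDRG1 at 1.68 (transcripts at 0.54 and 2.82), HK2 at 1.02 (transcripts at 0.027 and 2.01) and PDK1 at -1.96 (transcripts between -2.99 and 4.24). Nuclear-encoded genes of oxidative phosphorylation had a median of 0.115 over 24 genes. These last 3 lists lay inside the random lists, but the glycolysis and hypoxia list lay above them at tie limits of 1, 2, 10 and 50, and the oxidative phosphorylation list under 3 alternatives.

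Of 30 cytosolic ribosomal protein genes 28 were positive, by small amounts, with a median of 0.21 (1.15-fold), above 9999 of 10000 random lists. All 13 with 1 transcript were positive in the authors' deposited table. A list of long noncoding RNAs, fixed as nuclear-retained and as a sign of RNA quality, had a median of 0.44 over 9 genes. It lay above 9990 of 10000 random lists, with 6 positive. Where these RNAs lie in the cell was not measured, and whether the median reflects RNA quality was not tested. NEAT1 stood at 0.69, MALAT1 at 0.17, SNHG1 at 0.53, GAS5 at 0.52, SNHG5 at 0.44 and SNHG12 at 3.51, the last from 1 fine-valued transcript of 8. The 4 hosts of small nucleolar RNAs (SNHG1, SNHG5, SNHG12 and GAS5) were all positive, and SNHG5 gave the median. Of the other 5 members 3 were negative, NORAD at -0.037, OIP5-AS1 at -0.24 and TUG1 at -0.27. The list's median of 0.44 was measured between the same 2 libraries as every other group described here. Unfolded protein response genes had a median of 0.11 over 18 genes, heat shock genes one of -0.06 over 14 and immediate early genes one of -0.06 over 15, all inside the random lists. Integrated stress response genes had a median of 0.13 over 27 genes, with SLC7A11 at 0.88 and the asparagine synthetase gene ASNS at 0.72. Autophagy and lysosome genes had a median of 0.15 over 21 genes, with the kinase gene ULK1 at 0.74 (transcripts between -0.013 and 2.14). Circadian clock genes had one of 0.16 over 18. Among them were RORC at 1.40 (transcripts at 0.028 and 2.78), BMAL1 at 1.01 (1 fine-valued transcript of 48) and NPAS2 at -0.87 (transcripts between -1.09 and -0.039). These 3 lists lay just above the random lists (percentiles 98.0, 97.8 and 97.9) and each returned inside under at least 1 alternative.

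Markers of mammary lineage differed by list. Luminal markers had a median of 0.07 over 18 genes, inside the random lists, none of them met the rule of size, and the pioneer factor gene FOXA1 stood at 0.07 and EPCAM at -0.14 in the authors' deposited table. ESR1, the estrogen receptor gene, had a median of -0.70 over 10 transcripts that ranged from -7.45 to 0.27. Of 15 basal and myoepithelial markers 5 were measured, all negative, with a median of -1.27, below 9996 of 10000 random lists. They were EGFR (-5.47, 1 fine-valued transcript of 11), KRT17 (-2.13), KRT15 (-1.27), ACTA2 (-0.89) and CAV1 (-0.61). With 50 ties allowed, 8 were measured and the median was -0.13, inside the random lists, and with no tie limit 11 were measured and the median was -0.88, below them. Early estrogen response genes had a median of -0.45 over 25 genes, below all 10000 random lists, with 15 negative, among them PDZK1 (-1.65), the transcription factor gene MYB (-1.09, 1 fine-valued transcript of 18) and the progesterone receptor gene PGR (-0.52). Among the 11 with 1 transcript the median was 0.19, so the direction of this list was not stable, and the classical target TFF1 stood at 0.59 in the authors' deposited table.

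Of 19 breast cancer stem cell markers 11 were measured, with a median of -0.02, inside the random lists. ALDH1A3 stood at -1.65, ABCG2 at 1.04, MYC at 0.58 and CD44 at -0.30, the last from 15 transcripts between -5.69 and 8.09, while the stem cell factor genes SOX2 and BMI1 both stood at -0.02 in the authors' deposited table. Of 20 genes of the epithelial to mesenchymal transition 8 were measured, with a median of -0.13, inside the random lists. Among them were the fibronectin gene FN1 at -2.33 (1 fine-valued transcript of 18) and TGFB2 at 1.07. Of 13 Notch targets 8 were measured, with a median of -0.21, also inside the random lists. Wnt targets lay below the random lists, with 9 of 16 genes measured, a median of -0.40 and 7 negative. These included TNFRSF19 at -1.69 (1 fine-valued transcript of 10) and the Wnt antagonist gene DKK1 at -1.27. Of 10 Hedgehog pathway genes 3 were measured, GLI3 (-0.89), SHH (-0.44) and SUFU (0.12).

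Of 21 NF-kB targets 12 were measured, 10 of them negative, with a median of -0.27, CXCL1 at -1.28 and RELB at -1.15. Targets of p53 had a median of -0.23 over 21 genes, 17 negative. Among them were FAS at -1.04 (1 fine-valued transcript of 19) and the cell cycle inhibitor gene CDKN1A at -0.61. These lists and the Wnt list lay below the random lists by the median and inside them by the mean. STAT3 targets had a median of -0.19 over 15 genes, with the feedback inhibitor gene SOCS3 at -1.13. Apoptosis regulators had one of -0.07 over 24, with APAF1 at -0.87 (transcripts between -1.88 and 0.76). Both lists lay inside the random lists. Markers of other cell types were hardly measured. Fine-valued transcripts were present for 3 of 12 fibroblast markers (COL6A3 at -1.02, FBLN1 at -0.75 and COL1A1 at -0.15), 1 of 12 leukocyte markers (CD68 at -0.79) and 1 of 10 endothelial markers (ESAM at -0.50). None of the 13 mitochondrially encoded genes had a value here.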

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

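The tests of the tie limit, of the choice of transcripts and of GC content and length were chosen after the table had been seen; the others were planned. No paired analysis was possible because each arm has 1 library, and leaving out a library leaves no comparison. Alternatives chosen earlier that need levels or counts (pseudocounts, level minimums, other scalings, random lists in 10 bins of mean level, another unit, repeat columns and a count model) were not run, since the table's per-sample columns were not used. Of 17 lists outside the random lists, 7 stayed outside under each of the 11 to 14 alternatives that gave a value. The G2 and M phase list ranged from -1.52 to -1.35 and the S phase list from -1.07 to -0.71. The interferon list ranged from -1.48 to -1.18 and the aryl hydrocarbon receptor list from 0.57 to 1.22. The cholesterol list ranged from 0.26 to 0.40 and the ribosomal protein list from 0.18 to 0.23. For the long noncoding RNA list the range was 0.28 to 0.59. The early estrogen response list turned to 0.19 among genes with 1 transcript. With the mean in place of the median, 7 lists came inside: p53 (-0.25), estrogen (-0.24), Wnt (-0.44), NF-kB (-0.42), NRF2 (0.13), circadian (0.21) and autophagy (0.16). The NRF2 list also came inside without matching (0.13), with 50 ties (0.14), with no tie limit (0.14), among genes with 1 transcript (0.12) and with means over transcripts (0.115). The circadian list came inside at tie limits of 1 (0.108), 2 (0.083), 10 (0.095) and 50 (0.095), with no limit (0.065), among genes with 1 transcript (0.25), with means over transcripts (0.14) and with curated transcripts (0.083). The integrated stress response list came inside at a tie limit of 10 (0.103), with means over transcripts (0.107), with curated transcripts (0.103) and without transcripts past p of 0.05 (0.103). The autophagy list came inside with no tie limit (0.19) and after the GC and length trend was removed (0.11), the basal list with 50 ties (-0.13) and the drug metabolism list with no tie limit (0.18). The causes were not tested. Lists inside the random lists moved outside in 25 cases and stayed inside in 161. The 25 were 8 for fatty acid synthesis, 4 each for Notch and for glycolysis and hypoxia, 3 each for oxidative phosphorylation and histones, 2 for STAT3 and 1 for apoptosis. The fatty acid synthesis list, at 0.16, turned to -0.24 with 10 ties and -0.27 with 50, below the random lists. In the rest of its 8 cases it lay above them. Genes past the rule of size, 318 positive and 611 negative, became 851 and 1306 at 1.5-fold and 91 and 126 at 4-fold, by the construction of those thresholds. They became 23 (1.03%) and 62 (2.77%) of 2235 genes with 1 transcript, and 1921 and 2346 with no tie limit; with 50 ties the positive ones were 558. The authors' count of 0 became 11524 at an unadjusted p of 0.05. The median of all genes stayed within 0.1 of -0.02 in the alternatives run for it. For the 24 named genes, 45 of 48 alternatives kept the gene's side of the rule of size. BHLHA15, at 1.14, became 0.996 and POLN, at 0.95, became 1.02 after the GC and length trend was removed, and CYSRT1, at 0.996, became 1.014 after centring.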

Other observations

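All tests in this part were chosen after the lists' values had been seen. For GC content and length in the G2 and M phase and interferon lists, the deciding outcome was written before the test's own result was seen. Further gene groups, chosen after the fixed lists had been examined, gave more values for genes of cell division. All 10 mitotic kinesin genes were negative, with a median of -1.48 and KIF14 at -3.35. Of 21 centromere and kinetochore genes 19 were negative, with a median of -1.12, including KNL1 at -1.86. Of 13 homologous recombination and Fanconi genes 12 were negative (median -0.94, EXO1 at -2.09 from 1 fine-valued transcript of 23), and of 13 condensin and cohesin genes 11 were (median -0.62, NCAPH at -1.43). The first 3 of these groups lay below all 10000 random lists, and the condensin and cohesin group below 9999 of them. Genes of quiescence and cell cycle inhibition had a median of -0.04 over 10 genes, inside the random lists.

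Class I antigen presentation genes, many of them inducible by interferon, were all negative. Their median over 13 genes was -0.57, below all 10000 random lists. PSMB9 (-1.73) and HLA-B (-0.99) have 1 transcript in the authors' deposited table, PSMB8 stood at -1.02 and TAP1 at -4.19 from transcripts at -7.60 and -0.78, while B2M stood at -0.14. The constitutive proteasome core, with a median of -0.07 over 14 genes, and translation factors, with 0.12 over 14, lay inside the random lists.

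Most transcripts with an unadjusted p under 0.05 came from genes with many transcripts. If whole genes had changed, the other transcripts of the gene would go the same way. Over 10227 such transcripts with another fine-valued transcript in the gene, whatever its p, the median of the others in the direction of the transcript was -0.035 (quartiles -0.36 and 0.26), and 46.8% of these medians shared the direction, which argues against a change of the whole gene as the source of the pattern. Reads divided differently among near-identical isoforms in each library and regulated choice of transcript under treatment cannot be told apart, because there is 1 library per arm.

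For the negative G2 and M phase list, division of reads among isoforms is argued against by the members with 1 transcript, whose median was -1.52 over 7 genes, and a GC content or length trend by the median after both trends were removed, -1.35. For the S phase list, the median after both trends were removed was -0.82, still below the random lists, which argues against those trends as the whole source. Of its 10 members with a negative median over at least 2 fine-valued transcripts, 7 (70%) were negative in each, but 927 of 10000 random draws of genes with a negative median and as many such transcripts (5 or more as 1 class) reached that number, against a mean of 45.1%. Division of reads therefore stays open for this list, whose 4 members with 1 transcript were all negative, with a median of -0.71, and are few. For both lists a difference between the 2 cultures or libraries other than treatment, in cell density or sphere size for example, cannot be told apart from an effect of nobiletin, because there is 1 library per arm.

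For the negative interferon list, the signs within genes were counted to examine division of reads among isoforms. Of 14 members with a negative median over at least 2 fine-valued transcripts, 12 (85.7%) were negative in each. Of 10000 such random draws 0 reached that number, against a mean of 28.95%. That met the outcome set for arguing against division of reads, fewer than 2.5% of draws. The outcome is set aside here, because these draws were not matched on how negative the median was. A strongly negative median by itself makes negative signs in every transcript more likely, so the draws cannot decide. Division of reads stays open for this list. Its 3 members with 1 transcript were all negative, with a median of -1.25, and are few. After the GC content and length trends were removed the median was -1.24, which argues against those trends. A difference between the 2 cultures or libraries other than treatment cannot be told apart from an effect of nobiletin, with 1 library per arm.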
